A study of Homo sapiens with 14 samples.

How the data were processed

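The data came from left ventricular tissue of 7 human hearts, 3 labelled healthy and 4 labelled failed. By the labels each heart gave 1 CAGE library and 1 RNA-seq library, 14 libraries in all. CAGE (cap analysis of gene expression) sequences the capped 5' ends of transcripts, so that tags pile up at transcription start sites, while RNA-seq samples fragments along whole messenger RNAs. Per the labels' protocols, RNA was extracted with TRIzol and a column kit, CAGE libraries were made with the nAnT-iCAGE protocol, and RNA-seq libraries with a stranded mRNA kit. Different hearts are different people, so that each group's spread is a spread between donors as far as the labels hold. In CAGE this is open, because 1 library did not match the RNA-seq of its heart and may come from another heart. The submitters' processing notes name STAR 2.5.2, Trimmomatic, HTSeq and edgeR and the genome build hg19, without the role of each tool. The caller that grouped CAGE tags into clusters and the gene annotation are not given in the sources used here. All coordinates below are hg19, counted from 1, as the authors deposited them.

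The authors deposited 3 tables. The promoter table holds whole CAGE tag counts per promoter cluster and library, with each cluster's gene, and the authors' usage value, a fraction of the gene's tags that came from that cluster. Each of its 17111 clusters was seen in at least 3 libraries. Recomputed shares differed from the deposited fractions by at most 5.0e-10. The enhancer table holds whole CAGE tag counts for 1798 bidirectional clusters, 1371 of them in introns and 427 intergenic, together with the authors' own log2 fold changes and p-values. Each was seen in at least 2 libraries and its 2 strands were nearly balanced, with a balance score of at least 0.95. Each table also has a pooled score, a signal that the authors deposited as TPM, here CAGE tags scaled to library size and summed over the 7 libraries, and the promoter table has pooled tag counts. The RNA-seq table holds values for 14573 genes that the authors deposited as CPM, with their own log2 fold changes and p-values. The columns of that table did not sum to the same total in each library, so its values were treated as a signal on a scaled CPM, relative to library sizes that the authors had adjusted. In each library the deposited values were whole multiples of 1 step within a tolerance of 0.05 (100% of values), from which whole reads were recovered for use in alternatives.

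Total recovered RNA-seq reads per library ranged from 28834419 to 41211787. CAGE tags in the promoter table ranged from 14373699 to 35673464 per library, between 82.6% and 84.9% of the full library totals recovered from the pooled score. Failed replicate 4 had the fewest CAGE tags. Enhancer tags ranged from 4768 to 15483 per library, and the median enhancer had 12 tags over all 7 libraries, so that most enhancers could not be tested. Gene symbols were taken from Ensembl gene IDs: 14249 genes of the RNA-seq table matched a current symbol and 42 more an entry of GENCODE 29. The gene and promoter tables each had 16 entries, Y-linked or of the X-inactivation transcripts, that were left out before testing, and 1 Y-linked enhancer was left out. Transcript GC content and length came from GENCODE 29 on a newer build and were used by gene ID only.

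Before the data were examined, the tests, the gene lists, the rule for named genes and most alternatives were fixed. The plan named a count model or limma for RNA-seq depending on the unit found. Because the deposited unit was a scaled CPM, RNA-seq genes were tested with limma (trend, version 3.58.1, in R 4.3.3) on log2(value + 1), and fold changes are on that scale, which understates the change of genes with low values. Promoters and enhancers were tested on tag counts with edgeR's quasi-likelihood test (version 4.0.16, TMM normalization and edgeR's default filter). Enhancer library sizes were those of promoter and enhancer tags together. The promoter test covered 17095 clusters and the enhancer test 198. Promoter counts were also summed per gene (12908 genes) and tested in the same way. Promoter usage was tested with edgeR's diffSpliceDGE (gene-level Simes test) in 2374 genes with more than 1 promoter, over 5278 promoters that each held at least 5% of their gene's tags on average. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are failed over healthy, and errors of fold changes are standard errors (SE). Levels are means ± SD over 3 healthy and 4 failed libraries, in the deposited scaled CPM for RNA-seq and in TMM-normalized CPM for CAGE.

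The 30 fixed lists comprised 17 pathways or programs (fetal stress program, sarcomere, extracellular matrix, calcium handling and ion channels, fatty acid oxidation, glycolysis, nuclear-encoded oxidative phosphorylation, TCA cycle and ketone use, mitochondrially encoded genes, immediate-early genes, heat shock, acute-phase inflammation, interferon response, complement and antigen presentation, cardiac transcription factors, cardiomyopathy genes, and Wnt and TGF-beta signalling) and 13 sets of cell type markers (cardiomyocyte, fibroblast, endothelial, smooth muscle and pericyte, macrophage and monocyte, lymphocyte, mast cell, adipocyte, Schwann and neural, erythroid, atrial myocyte, epicardial, and skeletal muscle). They were tested with limma's camera at a preset inter-gene correlation of 0.01 where at least 3 members were measured, which left 29 lists in RNA-seq and 27 in CAGE. Some genes belong to more than 1 list: LUM to the matrix and fibroblast lists, MYH6 to the fetal, sarcomere and cardiomyocyte lists.

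The text names, for each comparison, up to 10 features with the highest and 10 with the lowest fold change (5 and 5 for enhancers) among those past the threshold, with a mean level at or above the median and every failed library on the same side of every healthy library. It also names up to 4 members of each list with the smallest adjusted p, all measured members of the fetal stress program, the 10 genes with the smallest adjusted p for promoter usage, and the changed enhancers with the nearest promoter within 500 kb. Y-linked genes, X-inactivation transcripts, HLA genes and genes with common germline deletions were never named. TUBA3D and TUBA3E are near-identical paralogs and PRODH has a related pseudogene, so that reads could be split between copies and their values are uncertain.

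The fold changes of both assays were correlated across genes on the log2(value + 1) scale, and each tested enhancer was paired with the nearest promoter. Both relations, and each count of calls, were also computed for all 35 splits of the 7 hearts into groups of 3 and 4. For promoters and usage only the splits that keep the 2 closest CAGE libraries together were counted, a restriction added after the data had been seen. Alternatives covered normalization, filters, pseudocounts, the test (DESeq2 1.42.0 among others), library sizes, usage minimums, pairing distances and leaving out each library in turn. A GC correction of the RNA-seq values, which removed from each library a loess trend (span 0.5) of log2 level on transcript GC in 14275 genes, was added after the data had been seen, as were count tests on the recovered reads, full library totals, another usage test and host gene pairing.

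Each test was checked on simulated data with 200 changed features drawn from the real means. Features and libraries were drawn independently, without correlation between genes, a GC trend or CAGE libraries that resemble each other. The rates below hold for that setting and can be too favourable for the real data. In the RNA-seq test 94% of genes changed by a log2 of 3 and 69% of those changed by 1.5 were recovered, with 6.32% false calls. For promoters 96% and 69% were recovered, with 6.25% false calls. In the simulated enhancers (225 tested) only 35 of the larger and 20 of the smaller changes passed the filter. Of these, 100% and 50% were recovered, while the other changed enhancers were not tested and could not be called. Usage changes were recovered in 88.2% and 38.7% of the changed genes that were tested (85 and 93). With no list changed, camera called 1 of 29 lists, and with the matrix list alone raised it called 3.

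Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used to read the tables and draw the figures.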

Results

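The series compared left ventricular tissue of healthy and failed human hearts to ask whether use of enhancers and promoters, and with them gene expression, differs in heart failure. Start sites and enhancers were read by CAGE and transcript levels by RNA-seq in libraries labelled as from the same 3 healthy and 4 failed hearts.

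Genes of the extracellular matrix were among the most strongly raised transcripts of the failed ventricles, and genes of fatty acid oxidation were among those that fell. Of 14557 genes tested by RNA-seq, 1071 passed the threshold, 696 higher and 375 lower in failed hearts (limma on log2 scaled CPM). LUM, which encodes the collagen-binding proteoglycan lumican, rose from 31.3 ± 18.3 to 261 ± 185 scaled CPM (SD, n = 3 healthy and 4 failed), a log2 fold change of 2.94 (SE 0.51, limma adjusted p = 0.0205). OGN (osteoglycin), a proteoglycan of the same family, rose by 3.24 (SE 0.39, limma adjusted p = 0.0117), from 4.02 ± 2.14 to 47.7 ± 25.3 scaled CPM. Their relative ASPN (asporin) rose by 2.75, the matrix-remodelling gene MXRA5 by 3.07, the matricellular THBS2 (thrombospondin 2) by 2.00 and the secreted protease inhibitor SERPINE2 by 2.10. The immediate-early transcription factor EGR1 rose by 2.83, PHLDA1 by 2.61, the calcium channel subunit CACNA2D1 by 2.14 and the P-type ATPase ATP13A3 by 2.03. By the rule that chose these 10 genes, every failed heart lay above every healthy heart in each. The CAGE fold change of CACNA2D1 was only 0.45 (SE 0.19, edgeR adjusted p = 0.261), and those of the other 9 lay between 1.91 and 4.83, none past the threshold.

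The genes that fell most were CYP4B1, a cytochrome P450 monooxygenase, and LCN10, a lipocalin. CYP4B1 went from 93.6 ± 38.1 to 6.72 ± 5.42 scaled CPM, with a log2 fold change of -3.84 (SE 0.60, limma adjusted p = 0.0167). LCN10 fell by 3.08, but its CAGE fold change was -0.48 (SE 0.30, edgeR adjusted p = 0.419). Transcripts of FCN3, a lectin of the complement system, fell by 2.84, those of the glycosyltransferase GALNT15 by 2.83 and those of ANKRD2, a stretch-responsive ankyrin repeat protein of muscle, by 2.58. The tubulin genes TUBA3E and TUBA3D had fold changes of -2.54 and -2.47. CBS (cystathionine beta-synthase), which condenses homocysteine with serine, fell by 2.01 (SE 0.22, limma adjusted p = 0.00866), and its CAGE value fell from 16.3 ± 3.50 to 2.87 ± 0.425 CPM, by 2.50 (SE 0.20, edgeR adjusted p = 0.0202). PRODH (proline dehydrogenase) and CPAMD8 fell by 2.01 and 2.02. CPAMD8 passed in CAGE as well, where it fell by 1.18 (edgeR adjusted p = 0.0249).

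In total 26.3% of the tested genes had every failed heart above (2141 genes) or below (1693 genes) every healthy heart. The average over all splits of the hearts is 5.71%. Genes vary together across hearts and the share was not computed for each split, so the difference is no test. RNA-seq fold changes followed transcript GC content, and after a per-library GC correction 118 of 14275 genes passed, 52 higher and 66 lower, of which 112 had also passed without it. Of the 20 genes named so far OGN, CACNA2D1, CYP4B1, GALNT15, TUBA3D, CPAMD8 and CBS passed after the correction, and of the further genes named for their lists COL15A1 and DPT. Leaving out healthy replicate 1 or healthy replicate 2 left 14 genes each, failed replicate 4 left 253, failed replicate 2 left 260, healthy replicate 3 left 262 and failed replicate 1 left 689. With GC correction, 106 genes passed in limma without failed replicate 3 and at most 2 without any other library, where at least 1754 had an unadjusted p under the threshold. In the authors' deposited table, 1158 genes had an adjusted p under the threshold, 772 higher in failed and 386 lower, of which 756 passed here too.

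**Figure D1:**
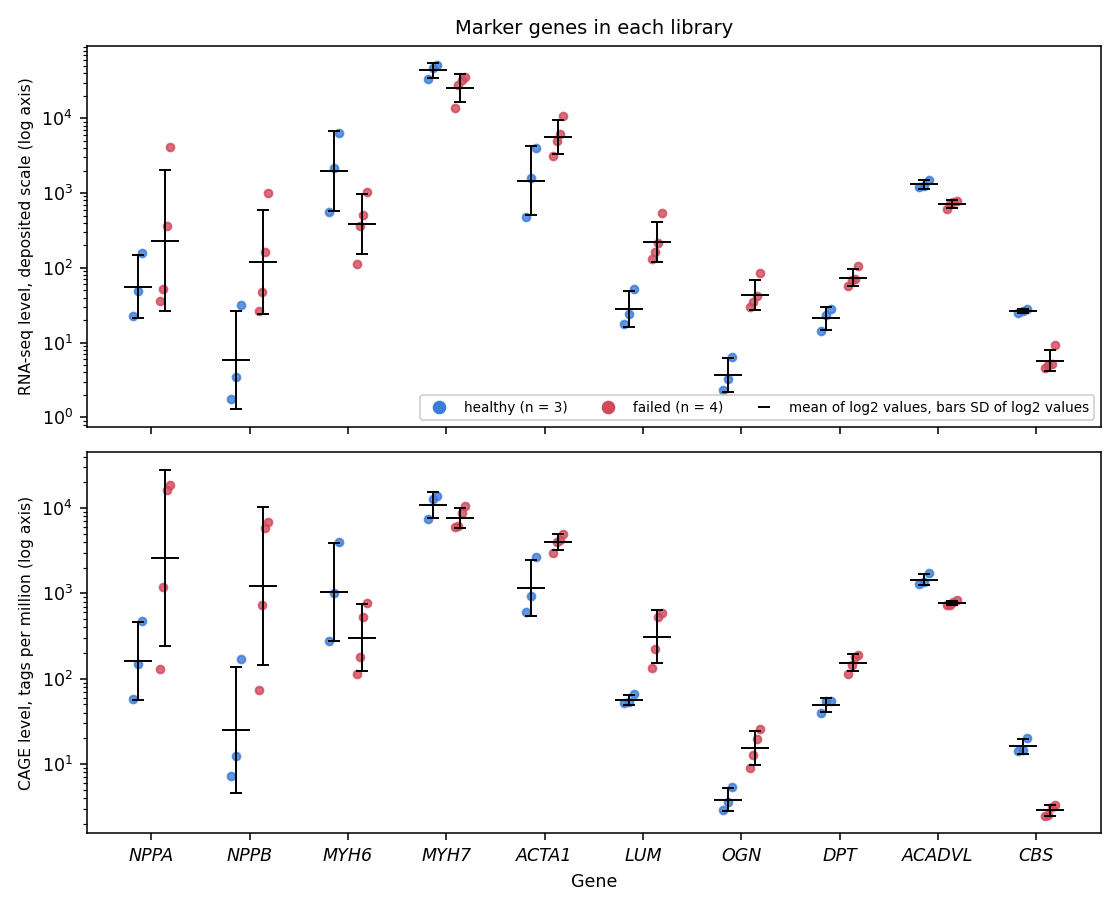
Levels of 10 marker genes in each library, RNA-seq in scaled CPM (top) and CAGE in CPM (bottom), both on log axes, with healthy hearts in blue (n = 3) and failed hearts in red (n = 4), sorted within each group. Black lines are means of log2 values with SD bars. LUM, OGN, DPT, ACADVL and CBS separate the groups in both assays, whereas NPPA, MYH6 and MYH7 overlap.

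The fetal stress program, a list that includes genes of the embryonic heart re-expressed under load, was not past the threshold as a group (median log2 fold change 0.75, 11 of 16 genes positive, camera adjusted p = 0.34). This test asks for a shared direction, so that members of opposite sign, such as ACTA1 and MYH6, offset each other. By limma's fry test of change in either direction the list had an adjusted p of 0.0779 in RNA-seq and 0.0385 in CAGE. A single gene of the 16 passed, adjusted over all genes and adjusted over the list alone: NPR3, the natriuretic peptide clearance receptor, rose by 1.27 (SE 0.25, limma adjusted p = 0.0278). It rose in CAGE too, by 1.62 (SE 0.23, edgeR adjusted p = 0.0332). The natriuretic peptide gene NPPB averaged 12.5 ± 17.1 scaled CPM in healthy and 307 ± 460 in failed hearts, with a log2 fold change of 4.02 (SE 1.29, limma adjusted p = 0.0954). NPPA averaged 76.1 ± 70.6 and 1130 ± 1964 scaled CPM, a fold change of 2.02 whose SE was 1.54 (limma adjusted p = 0.436). The CAGE fold changes of NPPB and NPPA were 5.72 (SE 1.87) and 5.32 (SE 1.72), likewise not past the threshold. Of the 2 CAGE libraries highest in both genes, 1 was the library that did not match the RNA-seq of its heart. The myosin heavy chain genes MYH6 and MYH7 had fold changes of -2.36 (SE 0.92) and -0.77 (SE 0.52), and skeletal alpha-actin (ACTA1) had 1.95 (SE 0.70). Of the remaining members, ANKRD1 (1.46), FHL1 (1.19), TNNI1 (1.27), XIRP2 (0.75), MYL7 (0.74), PLN (0.66) and MYL4 (0.42) had positive values and ATP2A2 (-0.76), CORIN (-0.78) and SERPINA3 (-0.39) negative ones, none past the threshold. PLN dropped to 0.05 after GC correction, and the signs of PLN, MYL7 and MYL4 changed under some settings.

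Among the lists past the threshold in RNA-seq, the extracellular matrix had the largest median. Its 42 measured genes had a median RNA-seq log2 fold change of 1.14, with 40 of them positive. 6 genes rose past the threshold over all genes and 11 adjusted over the list alone (camera adjusted p = 2.62e-07, and 0.746 as adjusted p with an estimated correlation). COL15A1, a collagen of basement membranes, rose by 1.85 (SE 0.32, limma adjusted p = 0.0207). Among failed hearts, replicate 3 had the highest RNA-seq level of LUM (534 against 132 to 212 scaled CPM), ASPN (122 against 24.5 to 42.6) and COL15A1 (164 against 86.4 to 143). After GC correction the median of the list was 1.15. In CAGE its median was 1.47 by edgeR, and 1.19 on the log2(value + 1) scale used for RNA-seq. There 39 of 40 genes were positive, none past the threshold over all genes and 20 adjusted over the list alone (camera adjusted p = 2.38e-11, and 0.686 as adjusted p with an estimated correlation). The CAGE library of 1 heart did not match its RNA-seq library, so that 1 failed heart may count 2 times in these CAGE values. Fibroblast markers were also higher, with a median of 0.88 and all 16 positive (camera adjusted p = 7.3e-05, and 0.746 as adjusted p with an estimated correlation). 4 of them rose over all genes and 9 adjusted over the list alone, while in CAGE 1 rose over all genes and 5 adjusted over the list alone. Dermatopontin (DPT), a matrix protein, rose by 1.75 (SE 0.27) in RNA-seq and by 1.66 (SE 0.22, edgeR adjusted p = 0.0308) in CAGE, from 49.8 ± 9.28 to 157 ± 35.6 CPM. The fibroblast genes NEGR1 and SCN7A rose in RNA-seq by 1.02 and 0.82. After GC correction they had 0.59 and 0.38 (limma adjusted p = 0.185 and 0.286), and their CAGE fold changes were -0.18 and 0.34, so that neither passed.

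Lists of energy metabolism lay lower in the failed ventricle. Of 31 genes of fatty acid oxidation, 27 had a negative RNA-seq fold change, with a median of -0.43 (camera adjusted p = 7.3e-05, and 0.746 as adjusted p with an estimated correlation). 3 fell over all genes and 7 adjusted over the list alone. After GC correction the median was -0.41 (camera adjusted p = 0.000119, and 0.712 as adjusted p with an estimated correlation), and 1 gene was lower adjusted over the list alone. ACADVL, the very long-chain acyl-CoA dehydrogenase of the inner mitochondrial membrane, fell from 1313 ± 177 to 719 ± 79.2 scaled CPM, by 0.87 on the log2 scale (SE 0.17, limma adjusted p = 0.0278), and in CAGE by 0.92 (SE 0.14, edgeR adjusted p = 0.0409). ACADS, the short-chain enzyme, fell by 0.85, and ACAA2, the last enzyme of the cycle, by 0.89, the latter with a CAGE value of 0.11. After GC correction ACADVL, ACADS and ACAA2 had -0.71, -0.67 and -0.96 and no longer passed (limma adjusted p = 0.128, 0.117 and 0.0536). For ESRRA, a nuclear receptor that regulates these genes, the fold change was -0.80 (limma adjusted p = 0.0512). The nuclear-encoded oxidative phosphorylation list had a median of -0.40 and 3 of 35 genes positive (camera adjusted p = 2.87e-05, and 0.746 as adjusted p with an estimated correlation), and no gene passed either over all genes or adjusted over the list alone. NDUFV2 (-0.68) and COX7A1 (-0.84) were its members with the smallest p. Glycolysis had a median of -0.40 (camera adjusted p = 0.0041, and 0.746 as adjusted p with an estimated correlation), and PGAM2 and ALDOC fell by 0.94 and 0.74, both also adjusted over the list alone. After GC correction the glycolysis median was -0.28 (camera adjusted p = 0.0423, and 0.799 as adjusted p with an estimated correlation). PGAM2 and ALDOC then had -0.76 and -0.60 (limma adjusted p = 0.129 and 0.0812). For the glucose transporter SLC2A4 the fold change was -0.99 (limma adjusted p = 0.083). The TCA cycle and ketone list (median -0.29, camera adjusted p = 0.00627, MDH2 -0.66) and the 15 mitochondrially encoded genes (median -0.44, camera adjusted p = 0.0212, MT-ND1 -0.78, MT-ND4L -0.79) had no gene past the threshold, and both had an adjusted p of 0.746 with an estimated correlation. Cardiomyocyte markers had a median of -0.33 (camera adjusted p = 0.0463, and 0.746 as adjusted p with an estimated correlation), with no gene past the threshold. In CAGE the lists of fatty acid oxidation (median -0.26, camera adjusted p = 0.000423), oxidative phosphorylation (-0.15, camera adjusted p = 0.0121) and the TCA cycle (-0.21, camera adjusted p = 0.0121) were lower, with adjusted p of 0.686, 0.797 and 0.797 with an estimated correlation. ACADVL was the only gene of the 3 lists past the threshold over all genes there, and 7 genes of fatty acid oxidation were lower adjusted over the list alone. Glycolysis was not past the threshold there (camera adjusted p = 0.21).

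Shifts upwards were found for immediate-early and interferon-response genes. The immediate-early list had a median of 0.92, with 21 of 22 genes positive (camera adjusted p = 0.00197, and 0.746 as adjusted p with an estimated correlation). Of its members EGR1 alone passed over all genes and none adjusted over the list alone, while NR4A3 (1.79), EGR2 (1.72) and BTG2 (1.41) did not pass. The interferon list had a median of 0.47 (camera adjusted p = 0.00335, and 0.746 as adjusted p with an estimated correlation), with 2 genes higher over all genes, and 10 higher and 1 lower adjusted over the list alone. IFI44L rose by 1.44 (SE 0.22, limma adjusted p = 0.0163) and OAS3 by 0.92 (SE 0.18, limma adjusted p = 0.0278), while OAS2 (0.77) and GBP1 (0.75) did not pass, with limma adjusted p of 0.0501 and 0.06. Both lists were higher in CAGE as well, with medians of 1.04 (camera adjusted p = 0.000156) and 0.50 (camera adjusted p = 8.55e-06), and 7 and 9 genes adjusted over the list alone, against 0 and 1 over all genes. The interferon list was the only list that passed by fry's test of direction in either assay (CAGE, fry adjusted p = 0.0377), and its adjusted p with an estimated correlation was 0.463 in CAGE, where the immediate-early list had 0.686. Wnt and TGF-beta genes had a median of 0.45 (camera adjusted p = 0.0426, and 0.746 as adjusted p with an estimated correlation). SKIL, a repressor of SMAD signalling, rose by 1.41 and the receptor TGFBR1 by 0.85. These 2 passed over all genes, and 3 genes of the list adjusted over the list alone. GC correction took SKIL to 0.78 and TGFBR1 to 0.52 (limma adjusted p = 0.181 and 0.192), and in CAGE they had 0.61 and 0.45 (edgeR adjusted p = 0.26 and 0.352). The list was not past the threshold in CAGE (median 0.27, camera adjusted p = 0.203), where 4 genes were higher and 1 lower adjusted over the list alone. WNT9A had a fold change of 1.94 (limma adjusted p = 0.0584).

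**Figure D2:**
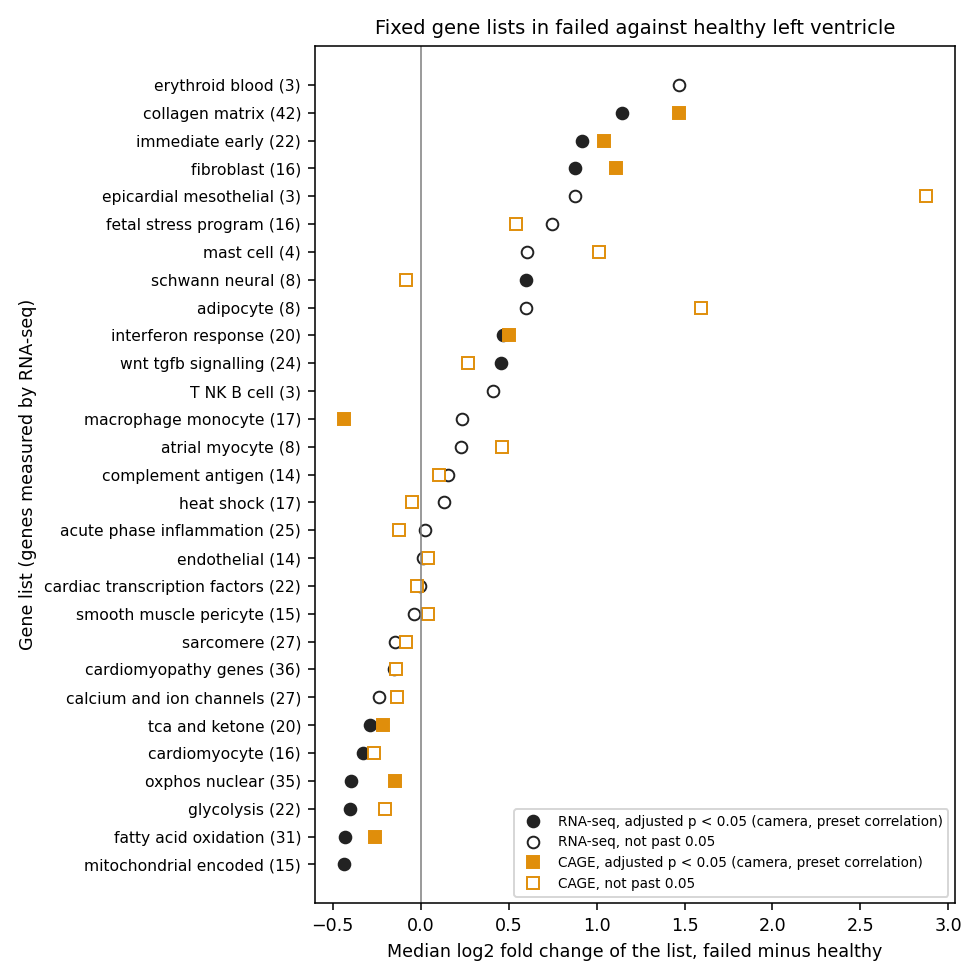
Median log2 fold change of each fixed gene list (horizontal axis, failed minus healthy), RNA-seq as circles and CAGE as squares. Filled symbols mark lists with a camera adjusted p under 0.05 at a preset correlation. The matrix list lies at 1.14 in RNA-seq and 1.47 in CAGE, and lists of energy metabolism lie below 0. RNA-seq values are on the log2(value + 1) scale and CAGE values are edgeR fold changes, so that sizes are not directly comparable.

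Few contractile and electrical genes passed. Of 27 sarcomere genes none passed (median -0.15, camera adjusted p = 0.0859), the smallest p belonging to TCAP (-0.86, limma adjusted p = 0.0611), then after MYH6 to DES (-0.74) and CSRP3 (0.85). Of the cardiomyocyte markers CKMT2 had -0.66, CKM -1.05 and TNNT2 -0.66. The list was past the threshold neither after GC correction (median -0.30, camera adjusted p = 0.13) nor in CAGE (camera adjusted p = 0.075). The 27 genes of calcium handling and ion channels had a median of -0.24 (camera adjusted p = 0.195). Of these KCNH2, a potassium channel gene of repolarisation, fell by 0.87 over all genes (limma adjusted p = 0.0426) but not adjusted over the list alone, and KCND3 had -0.98 (limma adjusted p = 0.0783). In CAGE 2 genes of this list were lower adjusted over the list alone. Of 36 cardiomyopathy genes, plakoglobin (JUP) fell by 0.96 (limma adjusted p = 0.0258) and the lysosomal LAMP2 rose by 0.54 (limma adjusted p = 0.0417), and the same counts, 1 higher and 1 lower, held adjusted over the list alone. LAMP2 had a fold change of 0.14 after GC correction and -0.05 in CAGE. Desmoplakin (DSP) had -0.78 (limma adjusted p = 0.0912).

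Start sites were compared next, from 17095 CAGE promoters. 140 passed, 40 higher and 100 lower in failed hearts (edgeR quasi-likelihood test). The number and balance depended on the test, since DESeq2 called 1357, 626 higher and 731 lower. Raised promoters included those of the chemokine gene CXCL2 (chromosome 4, 74964909 to 74964917, minus strand), with a log2 fold change of 2.82 (SE 0.47, edgeR adjusted p = 0.0453), and of the salt-inducible kinase gene SIK1, with 2.08 (SE 0.28, edgeR adjusted p = 0.0309). A promoter of GNAS, the gene of the stimulatory G protein alpha subunit (chromosome 20, 57464158 to 57464239, plus strand), rose by 2.01 (SE 0.18, edgeR adjusted p = 0.0174), from 6.60 ± 0.918 to 26.6 ± 4.30 CPM. The promoter of the Z-disc protein gene PDLIM3 (chromosome 4, 186456518 to 186456711, minus strand) rose from 304 ± 72.5 to 952 ± 154 CPM, by 1.65 (SE 0.21, edgeR adjusted p = 0.0297). Promoters of DPT (1.66), PRKAG2 (1.54), which encodes a regulatory subunit of AMP-activated kinase, the cytokine signalling inhibitor SOCS2 (1.53), PLEKHG1 (1.51), RASSF1 (1.31) and NPR3 (1.14) rose as well.

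The promoter that fell most was that of GNMT, glycine N-methyltransferase (chromosome 6, 42928449 to 42928493, plus strand). It went from 31.7 ± 18.0 to 1.30 ± 0.963 CPM, with a log2 fold change of -4.56 (SE 0.62, edgeR adjusted p = 0.0302). Promoters of SORBS2 (-2.54), ASB1 (-2.45), the mitochondrial carrier SLC25A34 (-2.37), the neutrophil and monocyte calgranulin S100A8 (-2.35), the kinase MARK3 (-2.34) and TRAPPC12 (-2.01) fell too. So did those of the anchoring protein AKAP13 (-1.85), the carboxylesterase CES2 (-1.83) and PALLD, the gene of the actin-associated protein palladin (-2.25, from 461 ± 97.1 to 96.9 ± 31.3 CPM). With promoters summed per gene, 83 of 12908 genes passed, 26 higher and 57 lower. In 1 of the 7 hearts the CAGE library did not match the RNA-seq library of the same heart: across genes, deviations from the mean of all hearts correlated at 0.179, against 0.698 to 0.846 in the other 6. Should that library come from another heart of the series, 1 heart would be counted 2 times in the CAGE comparisons. Without failed replicate 3 or without failed replicate 4 edgeR called no promoter, with 2651 and 2293 at an unadjusted p under the threshold. It called 4 without healthy replicate 1 or healthy replicate 2, 19 without failed replicate 2, 33 without healthy replicate 3 and 477 without failed replicate 1.

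Promoter usage, the share of a gene's CAGE tags that come from each of its promoters, changed in 19 of 2374 genes with more than 1 promoter (diffSpliceDGE, gene-level Simes test). In PALLD the failed hearts used the downstream promoter (chromosome 4, 169753121 to 169753334) for 27.5% ± 8.60 of tags against 76.0% ± 7.34 in healthy hearts (SD, n = 4 and 3). The upstream promoter (169418150 to 169418278) went from 20.3% ± 7.15 to 67.7% ± 10.2 (diffSpliceDGE adjusted p = 0.0222). In CPAMD8 the promoter at 17137576 to 17137685 on chromosome 19 supplied 90.2% ± 2.85 of tags in healthy and 58.1% ± 4.19 in failed hearts, the rest coming from a promoter downstream on the minus strand (17007710 to 17007794, diffSpliceDGE adjusted p = 0.000446). IQSEC1, a guanine nucleotide exchange factor gene, lost use of its upstream promoter (chromosome 3, 13028583 to 13028665) from 22.3% ± 4.59 to 4.44% ± 1.76 (diffSpliceDGE adjusted p = 0.00373). In TRAPPC12 the downstream promoter that fell held 28.4% ± 1.86 and 10.8% ± 2.88. ARAP1 moved its use from the promoter at 72492856 to 72492964 on chromosome 11 (47.6% ± 2.16 to 22.5% ± 6.40) towards others (diffSpliceDGE adjusted p = 0.0345). The smallest p in ARAP1 belonged to another promoter (72414394 to 72414461, diffSpliceDGE unadjusted p = 3.64e-05), whose share did not separate the groups. Its share was 0.796%, 0.998% and 2.92% in healthy replicates 1 to 3. In failed replicates 1 to 4 it was 2.83%, 4.18%, 15.025% and 13.2%. Smaller shares shifted in AKAP13 (10.3% ± 3.33 to 2.95% ± 0.643 at the promoter that fell), SLC41A3 (9.26% ± 1.73 to 1.94% ± 1.22), PTPA (1.82% ± 0.359 to 8.45% ± 5.35), HMGN1 (12.8% ± 0.453 to 5.35% ± 0.597) and the endothelial phosphatase gene PTPRB (7.53% ± 1.80 to 18.4% ± 3.76). The PTPA share was 3.25%, 4.61%, 11.6% and 14.3% in failed replicates 1 to 4.

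Of the 19 genes, 4 passed in total CAGE tags and 3 in RNA-seq. The total CAGE fold change of PALLD was -0.78 (edgeR adjusted p = 0.0623) and its RNA-seq fold change -0.88 (limma adjusted p = 0.0632), while HMGN1 rose by 0.85 in total tags (edgeR adjusted p = 0.0411). Between 4 (without healthy replicate 2 or without failed replicate 4) and 43 genes (without failed replicate 1) passed when single libraries were left out. The count was 6 without healthy replicate 1 and 9 without failed replicate 3.

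**Figure D3:**
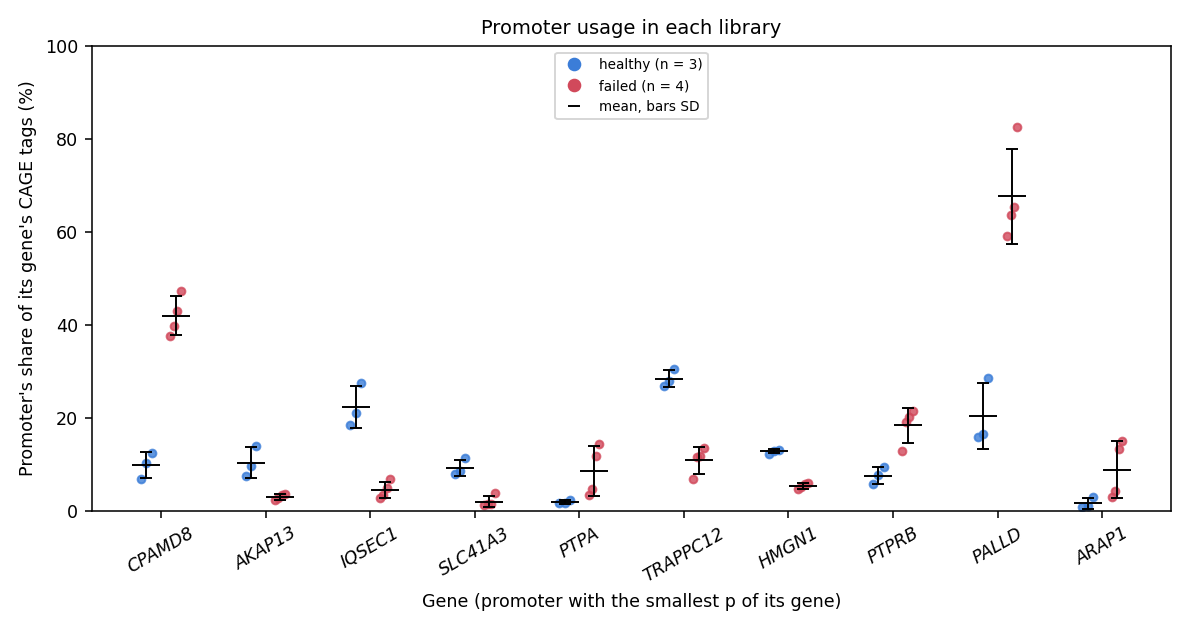
Share of a gene's CAGE tags (percent, vertical axis) from the promoter with the smallest p in each of the 10 genes with the smallest adjusted p, per library, healthy in blue (n = 3) and failed in red (n = 4), with mean and SD in black. The upstream promoter of PALLD supplied 20.3% of tags in healthy and 67.7% in failed hearts.

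Enhancers, read as pairs of divergent start sites in introns or between genes, carried few tags, and 198 of them could be tested. 3 fell in failed hearts and none rose (edgeR quasi-likelihood test), with 34 at an unadjusted p under the threshold. All 3 lie in first introns. The enhancer in LRRC2 (chromosome 3, 46606977 to 46607504) went from 2.56 ± 0.414 to 0.632 ± 0.287 CPM, with a log2 fold change of -1.99 (SE 0.40, edgeR adjusted p = 0.0321). Enhancers in ZHX2 (chromosome 8, 123794438 to 123794942) and AGFG1 (chromosome 2, 228337338 to 228337812) fell by 2.13 (SE 0.45, edgeR adjusted p = 0.0321) and 2.50 (SE 0.57, edgeR adjusted p = 0.0367). The AGFG1 enhancer had between 1 and 5 tags in each failed library. Nearest promoters, those of the same genes at distances of 542, 1032 and 692 bp, had fold changes of -0.08, 0.23 and -0.21, none past the threshold. The authors' deposited table gives 19 enhancers of 1797 with an adjusted p under the threshold, 6 higher and 13 lower in failed hearts, and the 3 named here are among them. Without healthy replicate 2, healthy replicate 3, failed replicate 3 or failed replicate 4 no enhancer passed in edgeR, with between 21 and 39 at an unadjusted p under the threshold, and 7 passed without failed replicate 2. With all libraries, DESeq2 called 11 enhancers, 3 higher and 8 lower.

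Over 195 pairs of an enhancer and the nearest promoter within 500 kb, log2 fold changes correlated across pairs with a Pearson r of 0.256 and a Spearman rho of 0.202, and 109 pairs (55.9%) had the same sign. Pairs are not independent replicates. Without failed or healthy libraries in turn, r lay between 0.147 and 0.285. At the promoter of PDLIM3, which rose, the enhancer 558 bp away in the first intron had a fold change of 2.08 (SE 0.68, edgeR adjusted p = 0.111). It was picked after its value was seen.

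Fold changes of the same genes in both assays correlated with a Pearson r of 0.697 and a Spearman rho of 0.602 across 11853 genes, which are not independent replicates, and 70.4% had the same sign. Of 588 genes called higher by RNA-seq and 22 called higher by CAGE, 14 were shared, where independent lists would share 1.09. Of 303 and 54 called lower, 46 were shared, with 1.38 from independent lists. Of the genes called higher by RNA-seq 79.6% were positive in CAGE, with a median of 0.18 against 0.80 in RNA-seq, and of those called lower 96.7% were negative, with a median of -0.63 against -0.86. Apart from the 1 heart whose libraries did not match, for which this is open, both assays used the same hearts, so that differences between donors are shared.

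**Figure D4:**
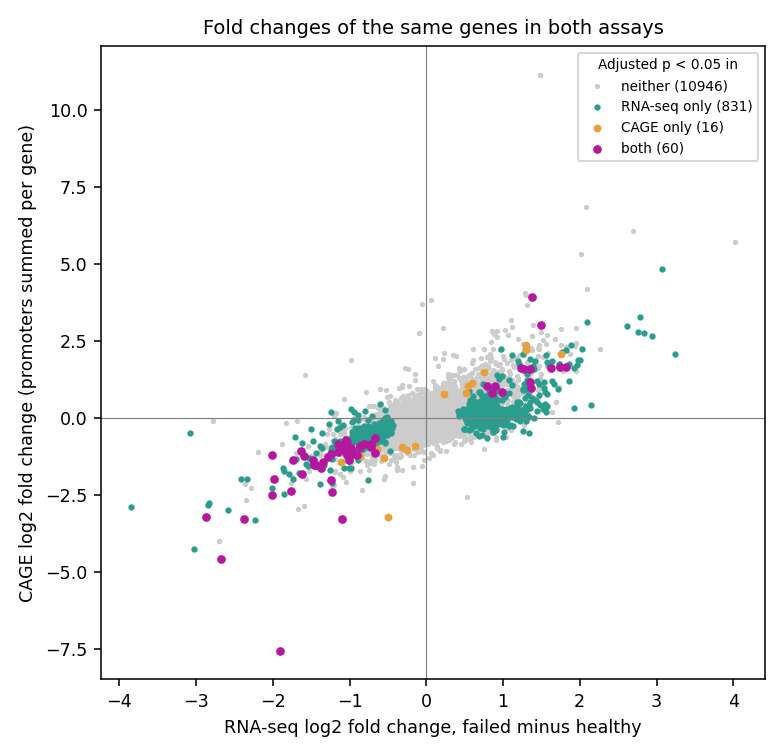
Log2 fold change by CAGE (promoters summed per gene, vertical axis) against RNA-seq (horizontal axis), failed minus healthy, 1 point per gene for 11853 genes. Colours mark genes past the threshold in both assays (60), in RNA-seq alone (831), in CAGE alone (16) or in neither (10946).

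RNA-seq fold changes fell with transcript GC content more steeply than CAGE fold changes of the same genes. Over 11124 protein-coding genes, the Spearman correlation of GC content and fold change across genes was -0.504 in RNA-seq and -0.177 in CAGE. With genes ranked by GC content and divided into 10 groups, median RNA-seq fold changes went from 0.46 in the lowest to -0.21 in the highest group and CAGE ones from 0.07 to -0.13.

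**Figure D5:**
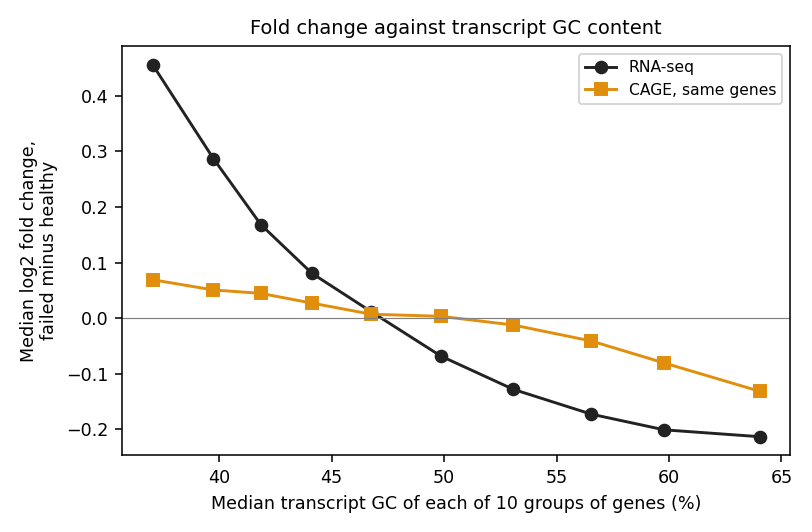
Median log2 fold change, failed minus healthy, of genes divided into 10 groups by transcript GC content (horizontal axis, median percent GC of each group), for RNA-seq (circles) and CAGE (squares) of the same genes. The RNA-seq curve falls from 0.46 to -0.21.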

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

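The tests in this part were chosen after the results they bear on had been seen.

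RNA-seq fold changes that follow transcript GC content are the first pattern, with a Spearman correlation of -0.504. Within RNA-seq libraries, the correlation of GC content with the deviation from the mean of all hearts was 0.503, 0.255 and 0.407 in healthy replicates 1 to 3 and -0.322, -0.355, -0.0579 and -0.529 in failed replicates 1 to 4. In CAGE libraries it was 0.161, 0.0135 and 0.184 in healthy and -0.0884, -0.174, -0.065 and -0.0636 in failed replicates, smaller in size in all but failed replicate 3 and of the same sign in each heart. A GC bias of single RNA-seq libraries would leave no trend in CAGE, and a true rise of GC-poor transcripts would leave one of unknown size. The 2 cannot be told apart, because the CAGE correlation in the same genes, -0.177, lies between none and the RNA-seq value. The sign of the trend followed the group in both assays, and other differences between the groups were not tested. Higher calls lost on correction had a median of 0.17 in CAGE against 0.78 in RNA-seq, but higher calls that the correction kept were compressed too (0.41 against 1.35). Lower calls lost on correction had a median of -0.80 in RNA-seq, -0.70 after the correction and -0.56 in CAGE, where 96.4% had the same sign, so that their loss speaks little for a GC bias. A chance division of the hearts is not excluded for this trend, since 3 of the 35 splits gave a correlation as large in size, the highest other being 0.584. Part of the 696 higher genes may reflect GC-dependent library differences.

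The mismatch between the CAGE and RNA-seq libraries of 1 heart is the second pattern. Its own correlation was 0.179, while the CAGE library correlated at 0.676 with the RNA-seq library of another heart, and no other pair of different hearts exceeded 0.270. Against a swap of CAGE libraries within the series, the lowest own-heart correlation of the other 6 hearts was 0.698. Another piece of the same heart is argued against by a separate check for mixed-up samples, which found 1 heart of 7 whose libraries did not match, the same heart. A CAGE library made from RNA of another heart stays open and may account for it: the library and that heart had the lowest biological coefficient of variation of the 21 pairs of CAGE libraries (0.142, next 0.229), against 0.338 between the same hearts in RNA-seq. The CAGE comparison would then rest on fewer independent failed hearts, with 1 heart counted 2 times in the 140 promoters, the 19 usage genes and the other CAGE results. The 2 CAGE libraries were no copies of each other. Of 10618 genes 16 differed between them by more than 4 times (39 to 244 in the other pairs), NPPA, NPPB and TNNI1 among them, and the tables do not settle which heart or which piece of it the RNA came from.

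The higher matrix genes are the third pattern, with a median of 1.14. A lower share of cardiomyocytes that left the other cell types in proportion should raise endothelial markers too. The endothelial median was 0.011 (quartiles -0.09 and 0.30), below the matrix quartiles of 0.62 and 1.45, which argues against that case only. Cardiomyocyte markers had a median of -0.33, with 4 of 16 positive, so that a lower share of cardiomyocytes with unequal changes in other cell types stays open. GC bias is argued against by the median of 1.15 after GC correction. More fibroblasts cannot be told apart from higher matrix expression per cell. The 7 fibroblast markers that are not matrix proteins had medians of 0.74 in RNA-seq, 0.38 after GC correction and 0.37 in CAGE. All 7 were positive in RNA-seq, but only 4 in CAGE (quartiles -0.09 and 0.38). How far these markers must rise for more fibroblasts to account for the matrix genes is not known, so that the values do not decide. Chance is not excluded either, with 3 of the 35 splits giving a median as large in size (highest other 1.22), and the disease itself remains a biological explanation that may apply.

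Within the 4 failed hearts, 21 of 221 groups of values had a single heart far from the other 3, by the gap to the nearest heart as a share of the range. For independent groups of normally distributed values chance gives 1 in 20, or 11.1 groups. Levels were compared without logs, where a high value stands out more, and some genes were counted in both assays. The excess over 11.1 is therefore no test. The lowest match of the 2 libraries of a failed heart stood at -0.0627, against 0.776 to 0.802 in the others (gap share 0.970).

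Failed replicate 2 was highest in RNA-seq levels of NPPB (991 against 26.0 to 162 scaled CPM, gap share 0.859), NPPA (4068 against 35.5 to 366, 0.918), TNNI1 (118 against 2.03 to 7.31, 0.955) and FCN3 (14.3 against 2.02 to 3.92, 0.846). It was also highest in CAGE levels of FCN3 (23.5 against 2.83 to 6.09 CPM, 0.842) and LPL (1987 against 1033 to 1064, 0.968). Failed replicate 3 was highest in RNA-seq levels of SERPINE2 (119 against 22.8 to 32.5, 0.899), THBS2 (81.0 against 23.6 to 27.9, 0.925) and BTG2 (304 against 71.3 to 106, 0.849) and lowest in KCND3 (gap share 0.892). In CAGE it was highest in S100A8, by gene (6.35 to 6.99 CPM in the others, 0.926) and by promoter (0.927), and in the share of the SLC41A3 promoter that fell (3.76% against at most 1.39%, 0.944).

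Failed replicate 4 was highest in RNA-seq levels of CBS (9.20 against 4.53 to 5.21, 0.854) and XIRP2 (1279 against 295 to 338, 0.957) and in the CAGE level of DES (9387 against 7991 to 8121, 0.907). Failed replicate 1 was highest in the RNA-seq level of CORIN (116 against 28.6 to 38.3, 0.889) and in CAGE levels of PLN (2488 against 1708 to 1741, 0.957) and KDR (61.5 against 17.1 to 22.8, 0.872), and lowest in SCN7A (99.6 against 136 to 141, 0.877).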

How the results depend on the processing

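Settings named below as added were chosen after seeing the data; the others were fixed. Leaving out a single library moved the counts to 14 to 1085 RNA-seq genes (0 to 106 with GC correction), 0 to 477 promoters, 0 to 7 enhancers, 4 to 43 usage genes, 7 to 14 lists in RNA-seq and 6 to 12 in CAGE, and the correlations to 0.637 to 0.727 between assays (lowest without failed replicate 3) and 0.147 to 0.285 between enhancers and promoters. RNA-seq gave 304 genes with an absolute log2 fold change of at least 1, and 118 with GC correction, 43 by edgeR on recovered reads with a GC offset and 2431 by DESeq2 on recovered reads (1456 higher, 975 lower), the last 3 added. Median centring gave 473 higher and 432 lower. DESeq2 called 1357 promoters (626 higher, 731 lower) and 11 enhancers. Enhancers numbered 8 of 1797 without a filter, 6 with totals without TMM and 5 with full library totals (added). Usage genes numbered 11 with rescaled library sizes, 5 and 42 with minimum shares of 10% and 1%, and 37 by voom and diffSplice (added). With an estimated correlation 0 lists passed in either assay, and by fry's test of direction 0 in RNA-seq and 1 in CAGE (interferon). By fry's test of change in either direction, interferon and Wnt and TGF-beta lists passed in RNA-seq (fry adjusted p = 0.00678 for both). In CAGE it gave adjusted p of 0.000523 for acute-phase, 0.000916 for interferon and 0.00153 for Wnt and TGF-beta genes. The fetal stress, fatty acid oxidation, cardiomyopathy and fibroblast lists had 0.0385 each there. It was not run over the splits of the hearts. Pairing enhancers with the host gene promoter (added) gave r = 0.186 over 113 pairs. The cause was not tested for any of these, apart from the smaller number of hearts when a library is left out.

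Healthy and failed hearts shared replicate numbers but not donors. Same-numbered hearts deviated together with r of -0.198, 0.0859 and 0.290 in RNA-seq and -0.0954, 0.156 and 0.300 in CAGE, and not every library correlated best with its own number, so the numbers do not pair the hearts. With the replicate number as a block, which leaves out failed replicate 4, 0 genes (limma, 3218 at an unadjusted p under the threshold), 0 promoters (edgeR, 2176), 1 enhancer and 1 usage gene passed.

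Of 1902 values of named genes in RNA-seq, 1895 kept their direction. The 7 that reversed belong to genes past no threshold: PLN (-0.0048 by edgeR with a GC offset), MYL7 (-0.13 without healthy replicate 2, the lowest of the left-out libraries, the highest being 1.29) and MYL4 (-0.39 without healthy replicate 2, with 1.63 as the highest, -0.14 with array weights, -0.47 by edgeR on recovered reads, -0.34 with a GC offset and -0.49 by DESeq2). All 280 values of named promoters kept their direction, 140 of them no longer past the threshold, as did 272 of usage genes (98), 50 of enhancers (17) and 200 of lists (60). Other settings stayed within 1.5 times the counts. Not run: RNA-seq without a filter, since the table was deposited already filtered, promoters without a filter, since all passed it, promoters restricted to those with a gene, since all have 1, and DESeq2 for usage, which it does not test. Depth limits which enhancers can be tested, with a median of 12 tags over 7 libraries.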

Other observations

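The splits of the hearts for the correlation between assays and for enhancer pairs were planned; the other tests in this part were chosen after the results had been seen.

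Fold changes of markers of other cell types had different signs, and few passed. Endothelial markers had a median RNA-seq log2 fold change of 0.01 (camera adjusted p = 0.851), with EMCN at 0.89 and KDR at -0.87. Those of smooth muscle and pericytes lay at -0.04 (HIGD1B -0.68). In RNA-seq no endothelial, smooth muscle or pericyte gene passed over all genes or adjusted over the list alone. Macrophage and monocyte markers had a median of 0.23 in RNA-seq, where CSF1R was 0.83, but -0.44 in CAGE (camera adjusted p = 0.00998, and 0.797 as adjusted p with an estimated correlation), where S100A8 (-2.34) and S100A9 (-2.20) were low and 4 genes were lower adjusted over the list alone. S100A8 and S100A9 lay lower in RNA-seq too, without passing. S100A8 had 2.23 to 6.73 scaled CPM in healthy and 0.565 to 2.15 in failed hearts, and S100A9 had 3.83 to 15.6 and 1.26 to 4.67. The mast cell receptor gene KIT rose by 1.25 (SE 0.25, limma adjusted p = 0.0284), from 0.711 ± 0.567 to 3.00 ± 0.723 scaled CPM, the only 1 of 4 mast cell genes to pass in RNA-seq, over all genes or adjusted over the list alone. Schwann and neural markers were higher in RNA-seq (median 0.60, camera adjusted p = 0.046, and 0.746 as adjusted p with an estimated correlation), with XKR4 up by 1.09 as the single gene past the threshold over all genes and 2 genes adjusted over the list alone, but had a median of -0.08 in CAGE. Medians of lists not past the threshold were 0.41 for 3 lymphocyte genes, 0.60 for 8 adipocyte genes (LPL 1.04), 1.47 for 3 erythroid genes (HBB 2.27, limma adjusted p = 0.0789), 0.23 for atrial myocyte genes (KCNA5 1.11) and 0.88 for 3 epicardial genes (WT1 0.88, limma adjusted p = 0.0504). HBB and WT1 passed adjusted over the list alone. After GC correction the erythroid list passed (camera adjusted p = 0.0141, and 0.712 as adjusted p with an estimated correlation). In CAGE 3 of 4 epicardial genes were higher and 1 lower adjusted over the list alone. The CAGE medians of the adipocyte and epicardial lists were 1.59 and 2.87, neither list past the threshold (camera adjusted p = 0.0828 and 0.21). The 4 skeletal muscle genes measured in CAGE had a median of 0.87 (camera adjusted p = 0.804).

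Stress and inflammation lists went both ways. Heat shock genes had a median of 0.13 (HSPB7 -0.56), complement and antigen presentation genes 0.16, cardiac transcription factors -0.0039 (GATA6 0.55) and acute-phase genes 0.02, with a mean of -0.17, since IL1RL1 stood at -2.72 (limma adjusted p = 0.0758) and S100A8 at -1.23 while NFKBIA (0.59) and TNFAIP3 (0.87) were positive. In RNA-seq none of these lists passed, and no gene of them did so over all genes or adjusted over the list alone. In CAGE none of the 4 lists passed by camera, nor did any of their genes over all genes. Adjusted over the list alone, 2 acute-phase genes were higher and 5 lower there, and 1 cardiac transcription factor gene was lower. The acute-phase list passed in CAGE by fry's test of change in either direction (fry adjusted p = 0.000523). The direction given by camera in RNA-seq was opposite to the sign of the median for endothelial markers, acute-phase genes and cardiac transcription factors. Mitochondrially encoded genes made up 33.7% ± 6.74 of RNA-seq values in healthy and 29.5% ± 3.37 in failed hearts (exact permutation test, p = 0.371). Enhancer tags made up 325 ± 48.4 CPM of the CAGE libraries in healthy and 301 ± 39.9 CPM in failed hearts (exact permutation test, p = 0.486). Of the tested enhancers, 117 of 198 (59.1%) had a negative fold change. Those in the first of the published enhancer sets marked in the authors' table had a median of -0.13 (88 enhancers) against -0.23 for the others.

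Among the 35 splits of the 7 hearts into groups of 3 and 4, only the real grouping gave 1071 RNA-seq genes. The highest other count was 1, and the same held for 118 genes with GC correction (highest other 1). A share of 1 in 35 is the smallest that these splits can give, so that chance is unlikely for both counts but not excluded. Because 2 CAGE libraries may come from the same heart, only the 15 splits that keep these together were counted for the 140 promoters (highest other 48, in a split that put failed replicate 1 with healthy hearts) and the 19 usage genes (highest other 14), in which 1 split, the real one, gave as many. 15 splits are too few for a share under 0.05. Chance cannot be excluded for the 3 enhancers, since 2 splits gave as many (highest other 4). Nor can it for the 12 lists in RNA-seq (27 splits, highest other 21) and the 8 lists in CAGE (19 splits, 20), which follow differences between single hearts about as often as the real grouping. The correlation of 0.697 between assays was reached by 16 splits (highest other 0.809), and that of 0.256 between enhancers and promoters by 5 (0.296).

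A general move to upstream promoters in failed hearts was a hypothesis from the usage genes, 12 of 19 of which used the most upstream promoter more. Over all tested genes 47.5% gained share there, which argues against it, and the mean share was 47.4% ± 0.234 in healthy and 47.1% ± 0.237 in failed hearts (exact permutation test, p = 0.114).

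Enhancers may be tied more closely to promoters nearby. Pairs under the median distance of 15313 bp had r = 0.331 (98 pairs) and those beyond r = 0.159 (97 pairs), a difference of 0.172 with a permutation p of 0.284 over 100000 resamples, which leaves the hypothesis open.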
